A study of Homo sapiens with 4 samples.

How the data were processed

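Chromatin was profiled by CUT&Tag, in which an antibody against a histone mark directs a protein A/G-tethered Tn5 transposase to cut and tag the DNA around it. The samples were 4 libraries of MV4-11, an established human acute myeloid leukaemia cell line. Cells had been kept for 7 days with 1 µM A-366, an inhibitor of the H3K9 methyltransferases G9a and GLP, or with its ethanol vehicle. Each treatment gave 1 library with an H3K9me2 antibody and 1 with an H3K27me3 antibody, so each group held 1 sample. No replicate, untargeted antibody control or spike-in control was analysed here.

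BWA, MACS2 and bcl2fastq are named without versions in the submitters' processing notes, with the genome build GRCh37 (hg19). Peaks were called separately in each library, as the authors deposited 1 narrowPeak list per sample. The caller's settings, duplicate handling and any control are not given in the sources used here. Each row holds a position, a fold enrichment (a ratio over the caller's own background) at the summit, a −log10 p-value and a −log10 q-value, all as deposited by the authors. The deposited score was 10 times the −log10 q-value cut to a whole number. The lowest −log10 q-value was 1.32, so the lists held no peak with a q-value above 0.05. The peaks stood on chromosomes 1 to 22, X and Y, with no overlapping or repeated rows. Fold enrichments and q-values were used within a list to describe, rank or filter its peaks, and were not compared as levels between lists.

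The lists carry no read totals, so the depth was read from the values themselves. MACS2 computes the fold as (summit pileup + 1)/(background + 1) and the p-value from a Poisson tail. For each peak the whole pileup that satisfied both deposited values was sought. A solution within 0.001 of the deposited −log10 p-value was found for 100% of the peaks in all 4 libraries. The background divided by the library's smallest peak width then gave a whole number of reads per 10 kb, within 0.02, for 100% of peaks above the genome-wide background. These read counts around peaks are inferred from the deposited values and count reads as the caller did. At a peak on the genome-wide floor, the value for its surroundings is an upper limit. In the H3K9me2 libraries a floor shared by 1046 vehicle and 384 A-366 peaks was the genome-wide background. With the caller's default effective human genome size of 2700000000 bases, assumed here, it implied 5.99 M reads for vehicle and 5.24 M reads for A-366. The ratio of 0.875 does not depend on that size. In both H3K27me3 libraries the lowest background was a whole read count, so the implied depth of 2.43 M reads was an upper limit only. The solver was tested on simulated data drawn from each library's own backgrounds. It returned 100% of the pileups, for 20285 and 17685 simulated H3K9me2 peaks (vehicle, A-366) and for 686 and 827 H3K27me3 peaks.

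Positions are given from base 1 on GRCh37. Peaks were counted as shared when they overlapped by at least 1 bp. The chance level came from 100 circular shifts of one list around each chromosome, whose length was taken to its last peak. With 30% of peaks planted as shared among randomly placed ones, the overlap count returned 30.3% of 18295 peaks at the H3K9me2 list sizes and 29.96% of 978 at the H3K27me3 sizes, and it equalled that of bedtools 2.31.1. Shares carry exact (Clopper-Pearson) 95% binomial intervals and counts of peaks exact 95% Poisson intervals. These cover counting error only, and neighbouring peaks are not independent, so they are too narrow. With 1 library per group no test between treatments was made and no p-value is given. Every difference below is a difference between 2 libraries.

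The gene table at hand is on GRCh38.p14, another build, so none of its coordinates were used and no peak was assigned to a gene. The planned promoter shares and counts of list genes with a peak were therefore not run. Its chromosome column gave the number of protein-coding genes per chromosome, which was divided by the length to the last peak. Intervals of rank correlations across chromosomes came from 1000 bootstrap draws of the peaks, and from 300 draws where reads per 10 kb entered. These intervals cover the sampling of peaks and not the spread between chromosomes. As laid down for this case before the data were examined, regions were described as bins of 1 Mb: per mark the 5 with the largest gain and the 5 with the largest loss of covered length, and per library the 5 peaks of highest fold. From the gene lists fixed at the same time, 13 intervals of whole megabases were also counted, all of which are reported. The lists covered MHC class I and II presentation, HOX genes, protocadherins, olfactory receptors, zinc finger genes and replication-dependent histones. The placement of these loci in the intervals is general knowledge of the GRCh37 map. It was written down after the lists had been opened and was not checked against an annotation of that build, and each interval also holds other genes. Lists without such a compact position, such as the CtBP complex, interferon response and lineage markers, were not analysed here. Alternatives were stricter q-value and fold limits, autosomes alone, merging of peaks within 5 kb, a 50% reciprocal overlap, a 1 kb tolerance, random placement, shifts of 50 to 500 kb, and equal numbers of the strongest peaks. Leaving out a replicate was not possible with 1 library per group. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.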

Results

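H3K9me2 and H3K27me3 were mapped by CUT&Tag in MV4-11 leukaemia cells after 7 days of A-366 or vehicle. Both marks are associated with silent chromatin. H3K9me2 is deposited by G9a and GLP, the enzymes that A-366 inhibits, and H3K27me3 by Polycomb repressive complex 2. The H3K9me2 lists held 20384 peaks for vehicle and 18295 for A-366, and the H3K27me3 lists 780 and 978. The depth implied by the H3K9me2 lists was 5.99 M reads for vehicle and 5.24 M reads for A-366. It was at most 2.43 M reads in each H3K27me3 library. The median H3K9me2 summit held 10 reads in vehicle and 12 in A-366, and the median H3K27me3 summit 19 and 18. At this depth a single H3K9me2 peak rests on few reads. Each group was 1 library, so no value below has a replicate error.

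The first comparison asked how H3K9me2 peaks differed after inhibition of G9a and GLP. The A-366 library held fewer peaks over the olfactory receptor clusters of 11p, 25 against 66 in vehicle, and the separate 95% intervals did not overlap. How often other windows of this size differ as much was not counted. A larger share of its peaks lay on chromosomes 16, 17, 19, 21, 22 and X. The MHC class II region held 11 peaks in each library. The largest gains of single megabases lay near the end of chromosome 8 and at the immunoglobulin heavy chain locus.

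The A-366 library held 10.2% fewer H3K9me2 peaks than vehicle, a ratio of 0.898 (95% interval 0.880 to 0.916). Its peaks were wider, with a mean of 431 bp against 388 bp, and they covered nearly the same length, 7877 kb against 7913 kb. Among peaks with a −log10 q of 5 or more the A-366 library held 1.36 times as many as vehicle, while with a fold of 5 or more the ratio was 0.784. The number of peaks therefore gave no direction of change for H3K9me2 that held at each threshold.

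Reads lay closer together around the H3K9me2 peaks of A-366-treated cells. The median number of reads in the 10 kb around a peak was 57 after A-366 and 41 in vehicle, at a lower implied depth. Over 4809 peaks that matched one to one between the lists, the reads per 10 kb were 1.61 times higher in the A-366 library (interquartile range 1.19 to 2.03) and were higher at 83.8% of them. Divided by the implied depths, the median ratio was 1.83. The summit pileup of the same peaks was 1.33 times higher (interquartile range 1 to 1.67). In the H3K27me3 libraries 417 matched peaks had a median ratio of 1.09 for reads per 10 kb and 1.06 for the summit, without a correction for depth. With no spike-in control analysed here, these values describe how reads were spread within a library and not the total amount of the mark.

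Individual H3K9me2 peaks overlapped little between treatments. Of the vehicle peaks, 24.8% (95% interval 24.3 to 25.4%) overlapped an A-366 peak, and of the A-366 peaks 27.5% (26.8 to 28.1%) overlapped a vehicle peak. Circular shifts gave 0.533% and 0.591%, so the observed overlap was 46.6 and 46.5 times the chance level. The share rose with the strength of the peak, from 17.6% in the lowest quintile of vehicle peaks by −log10 q to 38.8% in the highest, and from 15.2% to 48.9% for A-366 peaks. In bins of 1 Mb the covered lengths of the 2 libraries correlated with Pearson's r = 0.68 and Spearman's rho = 0.68 over 3106 bins, which are neighbours along chromosomes and not independent replicates.

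**Figure D1:**
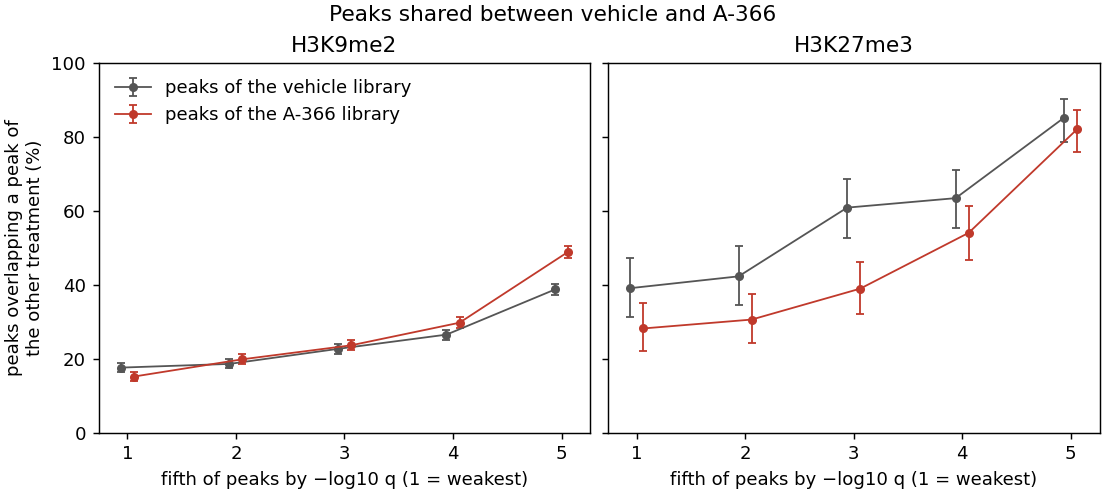
Share of peaks (%) that overlapped a peak of the other treatment, by quintile of the library's peaks ordered by −log10 q, for H3K9me2 (left) and H3K27me3 (right). Points are single libraries and bars exact 95% binomial intervals. The highest quintile of vehicle peaks reached 38.8% for H3K9me2 and 85.3% for H3K27me3.

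The share of H3K9me2 peaks on single chromosomes differed between the libraries. After A-366 it was larger on chromosomes 16, 17, 19, 21, 22 and X and smaller on chromosomes 2 and 8, with intervals that did not overlap. For the other 16 chromosomes the intervals overlapped. Chromosome 19 held 2.60% of the A-366 peaks (2.38 to 2.84%) and 1.41% of the vehicle peaks (1.26 to 1.58%). Chromosome 22 held 0.858% (0.730 to 1.00%) and 0.407% (0.324 to 0.505%). Chromosome 2 held 8.18% of the A-366 peaks and 9.52% of the vehicle peaks. The 5 autosomes with the most protein-coding genes per megabase, 11, 16, 17, 19 and 22, together held 11.7% of the peaks after A-366 (11.2 to 12.2%) and 9.09% in vehicle (8.70 to 9.49%). Of these 5, chromosome 11 held 4.27% after A-366 and 4.51% in vehicle. The 5 autosomes with the fewest held 24.9% and 25.6%, with overlapping intervals, although chromosome 21 among them held 1.301% after A-366 and 0.883% in vehicle. Across the 22 autosomes the log2 ratio of shares rose with gene density (r = 0.62, rho = 0.47). Without chromosomes 17 and 19, the farthest from the median density, r was 0.42 and rho 0.33. This relation was examined after the chromosome shares had been seen. Chromosomes are not independent replicates, and no p-value is given for it. The autosomes 16, 17, 19, 21 and 22 were also among the shortest, with 48.0 to 90.0 Mb to the last peak. Chromosome X, at 155 Mb, was not. Chromosome 21 had 4.97 genes per Mb and a share ratio of 1.47, and chromosome 11 had 9.64 and 0.948. Among the autosomes, the share was lower after A-366 on chromosomes 1 to 9 and 11, each 134.9 Mb or longer to the last peak. It was higher on chromosomes 10 and 12 to 22, all shorter than that except chromosome 10 (135.4 Mb, share ratio 1.05). The direction of the shift on autosomes therefore followed chromosome length closely. No correlation with length was computed, so a relation with gene density cannot be told apart from one with length.

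**Figure D2:**
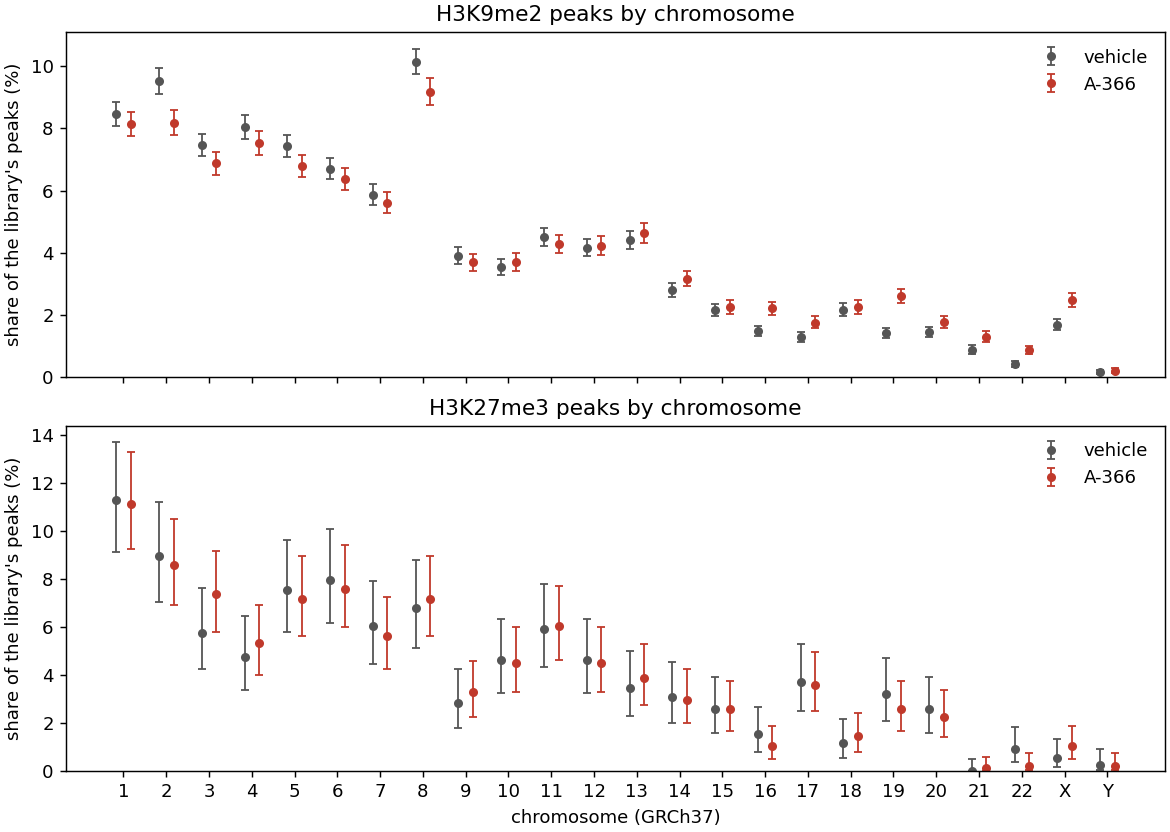
Share of each library's peaks (%) on each chromosome of GRCh37, for H3K9me2 (top) and H3K27me3 (bottom). Points are single libraries, grey for vehicle and red for A-366, and bars are exact 95% binomial intervals. The H3K9me2 share of chromosome 19 was 2.60% after A-366 and 1.41% in vehicle.

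The largest regional gains in the length covered by H3K9me2 peaks lay near the end of the long arm of chromosome 8. On GRCh37, the bin of chromosome 8 from 143000001 to 144000000 held 44 peaks over 25.4 kb after A-366 and 14 peaks over 5.73 kb in vehicle. Its neighbours also gained, from 2.41 to 12.975 kb at 142000001 to 143000000 and from 5.31 to 13.1 kb at 144000001 to 145000000. On chromosome 14 the bin from 106000001 to 107000000, which overlaps the immunoglobulin heavy chain locus on the general map, held 21 peaks over 12.9 kb and 3 peaks over 1.10 kb. On chromosome 1 the bin from 30000001 to 31000000 held 23 peaks after A-366 and 3 in vehicle. The largest losses lay in the interior of chromosomes 1, 7 and 8. The bin of chromosome 7 from 17000001 to 18000000 held 19 peaks in vehicle and 0 after A-366, a count whose 95% Poisson interval reaches 3.69. The bin of chromosome 8 from 60000001 to 61000000 held 27 vehicle and 8 A-366 peaks, that from 110000001 to 111000000 held 23 and 5, and that from 115000001 to 116000000 held 25 and 11. On chromosome 1 the bin from 219000001 to 220000000 held 21 and 4 peaks. The Poisson intervals of the libraries overlapped in the bins of chromosome 8 that start at 115000001 and 144000001 and not in the others. These bins were picked for their difference, so its size in them is overstated.

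Among 13 intervals placed over known gene clusters, the olfactory receptor clusters of 11p stood apart. These genes encode odorant receptors and are silent in most tissues. Chromosome 11 from 4 to 8 Mb held 66 H3K9me2 peaks in vehicle (95% interval 51.0 to 84.0) and 25 after A-366 (16.2 to 36.9), a ratio of 0.379 (0.229 to 0.608). Of the 66, only 7 overlapped an A-366 peak. The ratio stayed between 0.403 and 0.567 under stricter limits and with equal numbers of peaks, although its interval with a fold of 5 or more (0.293 to 1.06) included 1. The olfactory receptor clusters of 11q, at 55 to 60 Mb, held 34 and 26 peaks (ratio 0.765, interval 0.441 to 1.31). In the other direction, the zinc finger clusters of 19q13, at 52 to 59 Mb of chromosome 19, held 28 peaks in vehicle and 46 after A-366, a ratio of 1.64 (1.01 to 2.73). That ratio was 1 among peaks with a fold of 5 or more. The separate Poisson intervals of the 2 libraries did not overlap for the olfactory receptor clusters of 11p and overlapped for the other 12 intervals. These intervals are too narrow, and how often other windows of this size differ as much was not counted. The difference at 11p therefore cannot be tied to its olfactory receptor genes.

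The intervals around MHC genes address the subject named in the series title, MHC class II expression. The MHC class II region, chromosome 6 from 32 to 34 Mb, held 11 H3K9me2 peaks in vehicle and 11 after A-366, a ratio of 1 with an interval of 0.393 to 2.54. Only 1 of these peaks was shared, at 32503170 to 32503443 in vehicle. Among peaks with a fold of 5 or more the ratio was 0.222 (0.0234 to 1.07). The CIITA interval, chromosome 16 from 10 to 12 Mb, named for the transactivator of MHC class II genes, held 3 peaks in vehicle and 6 after A-366 (ratio 2, interval 0.427 to 12.4), none of them shared. The MHC class I region, chromosome 6 from 29 to 32 Mb, held 10 and 21 peaks (ratio 2.1, interval 0.947 to 4.99). Among peaks with a −log10 q of 3 or more it held 6 and 19 (ratio 3.17, interval 1.22 to 9.69), and with a fold of 5 or more 5 and 7 (1.4, 0.382 to 5.59). With equal numbers of the strongest peaks the ratio was 2.33 (1.02 to 5.79). With all peaks, neither a loss nor a gain in the number of H3K9me2 peaks was detectable in these 3 intervals. A peak is called against the reads around it, so a change spread evenly over a region could leave the counts unchanged. The counts therefore do not measure the level of H3K9me2 over a whole interval.

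In the remaining gene clusters the counting intervals of the libraries overlapped. The protocadherin clusters, which encode neuronal adhesion proteins, held 9 H3K9me2 peaks in vehicle and 17 after A-366. The histone cluster of 6p22 held 13 and 18, and the zinc finger cluster of 19p12 held 2 and 6. The HOXA cluster held 8 and 4, HOXB 1 and 0, HOXC 2 and 0, and HOXD 14 and 10.

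**Figure D3:**
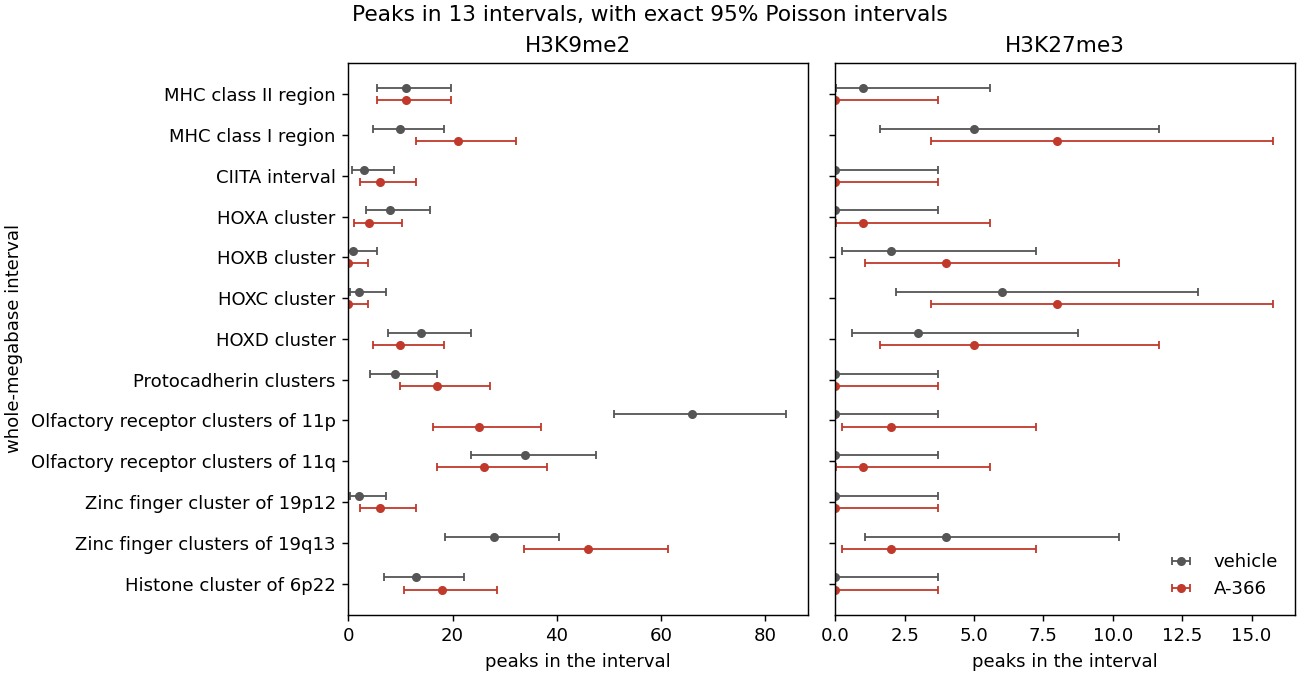
Number of peaks in 13 whole-megabase intervals placed over known gene clusters, for H3K9me2 (left) and H3K27me3 (right). Points are single libraries, grey for vehicle and red for A-366, and bars are exact 95% Poisson intervals. The interval of the olfactory receptor clusters of 11p held 66 H3K9me2 peaks in vehicle and 25 after A-366.

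The second comparison asked whether H3K27me3 differed between the same treatments. The A-366 library held 25.4% more H3K27me3 peaks, a ratio of 1.25 (95% interval 1.14 to 1.38), and they covered 478 kb against 399 kb. With a fold of 5 or more the ratio was 1.10. The depths of these libraries are known only as upper limits, so a deeper A-366 library could also give more peaks. Of the vehicle peaks, 58.2% (54.7 to 61.7%) overlapped an A-366 peak, and of the A-366 peaks 46.8% (43.7 to 50.0%) overlapped a vehicle peak. Circular shifts gave 0.0308% and 0.0256%. In the highest quintile of vehicle peaks the share was 85.3% (78.7 to 90.4%). No chromosome had a share of H3K27me3 peaks whose interval in one treatment lay apart from that in the other.

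Of the HOX clusters, transcription factor genes that are classical Polycomb targets, HOXB, HOXC and HOXD held H3K27me3 peaks in both libraries. The 5 Mb that hold the HOXA, HOXB, HOXC and HOXD clusters contained 11 H3K27me3 peaks in vehicle (95% interval 5.49 to 19.7) and 18 after A-366 (10.7 to 28.4). This was 8.72 and 11.4 times the genome-wide density of such peaks. HOXC held 6 and 8 peaks, a ratio of 1.33 that was 0.5 with equal numbers of the strongest peaks, HOXD 3 and 5, HOXB 2 and 4, and HOXA 0 and 1. For H3K9me2 the same 5 Mb held 0.758 and 0.473 times the genome-wide density. Of the other intervals, the MHC class I region held 5 and 8 H3K27me3 peaks, a ratio of 1.6 that was 0.5 with a fold of 5 or more. The zinc finger clusters of 19q13 held 4 and 2, and the MHC class II region 1 and 0. The olfactory receptor clusters of 11p held 0 and 2 and those of 11q 0 and 1. The CIITA interval, the protocadherin clusters, the zinc finger cluster of 19p12 and the histone cluster of 6p22 held 0 in both libraries, which allows up to 3.69 peaks each.

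The H3K27me3 bins with the largest differences held few peaks. The largest gain was on chromosome 5 from 72000001 to 73000000, with 6 peaks over 3.99 kb after A-366 and 5 over 1.82 kb in vehicle. Chromosome 2 from 119000001 to 120000000 held 4 and 1 peaks, and chromosome 13 from 20000001 to 21000000 held 5 and 3. Chromosome 4 from 56000001 to 57000000 and chromosome 14 from 57000001 to 58000000 each held 2 and 0. The largest losses were on chromosome 8 from 86000001 to 87000000, with 0 peaks after A-366 and 3 in vehicle, and on chromosome 19 from 54000001 to 55000000, with 1 and 3. Chromosome 19 from 3000001 to 4000000 and chromosome 8 from 142000001 to 143000000 each held 0 and 2. Chromosome 1 from 145000001 to 146000000 held 2 in each, over 0.708 and 1.69 kb. The Poisson intervals of the libraries overlapped in each of these bins.

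The peaks of highest fold were compared between treatments. All 5 of the highest H3K27me3 peaks of each library overlapped a peak of the other. They lay in vehicle on chromosome 19 at 29379131 to 29379635 (fold 9.76), chromosome 1 at 240348043 to 240348462 (9.72) and 232173457 to 232173921 (8.60), chromosome 7 at 12151362 to 12151992 (8.502) and chromosome 10 at 51488872 to 51489209 (8.502). After A-366 the highest was on chromosome 20 at 46523430 to 46524645 (fold 9.64, 54 reads at the summit). It was followed by the same 2 regions of chromosomes 7 (9.05) and 1 (8.98), chromosome 1 at 84543820 to 84544363 (8.93) and chromosome 22 at 51082067 to 51082517 (8.92). Of the 5 highest H3K9me2 peaks, 3 in each library had an overlap in the other. In vehicle these were on chromosome 5 at 178012300 to 178012916 (fold 11.9), chromosome 2 at 107980879 to 107981441 (11.5) and chromosome 4 at 104435835 to 104436310 (10.7). The vehicle peaks on chromosome 6 at 10202716 to 10203257 (10.9) and chromosome 2 at 98716687 to 98717215 (10.6) had none. After A-366, peaks on chromosome 10 at 134177698 to 134178317 (10.9), chromosome 7 at 149700270 to 149700986 (10.8) and chromosome 1 at 74015354 to 74015772 (10.7) had an overlap. Those on chromosome 13 at 36532085 to 36532587 (11.9) and chromosome 17 at 77134150 to 77134994 (10.9, 44 reads at the summit) had none. The difference in recurrence between the marks was not tested.

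The third comparison set the 2 marks against each other within a treatment. H3K27me3 peaks lay within 10 kb of H3K9me2 peaks less often than by chance, though this distance was not among the planned rules. In vehicle, 37 of 780 H3K27me3 peaks (4.74%, 95% interval 3.36 to 6.48%) lay within 10 kb of an H3K9me2 peak, where circular shifts gave a mean of 105 (75 to 133). After A-366 these were 55 of 978 (5.62%, 4.26 to 7.26%) against 114 by shifts (88 to 138). The observed numbers were 0.353 and 0.481 times the chance level, and both lay below the lowest of the 100 shifts. Direct overlap, the planned measure, was rare, with 8 peaks in vehicle and 3 after A-366. Chance gave 4.92 and 5.82, and the observed numbers lay inside the range of the shifts. Over the 3106 bins of 1 Mb the covered lengths of the 2 marks had r = -0.03 in vehicle and r = 0.00041 after A-366.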

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

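The relation with gene density and the tests on copy number and on a shift common to both antibodies were chosen after the values they use had been seen. With all peaks, the ratios of A-366 over vehicle below lay on opposite sides of 1 in the H3K9me2 and the H3K27me3 libraries. With 1 library per group these differences between the marks were not tested.

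The number of peaks was 0.898 times that of vehicle for H3K9me2 and 1.25 times for H3K27me3, and the covered length 0.995 and 1.198 times. These 2 contrasts depended on the threshold, and the depths of the H3K27me3 libraries could not be compared. With a −log10 q of 5 or more both ratios of peak number were above 1 (1.36 and 1.17), as were both of covered length (1.503 and 1.14). For covered length this also held with a −log10 q of 3 or more (1.07 and 1.15) and with peaks within 5 kb merged (1.04 and 1.196). The share of peaks on chromosome 16 was 1.495 times that of vehicle for H3K9me2 and 0.665 times for H3K27me3. On chromosome 17 the ratios were 1.37 and 0.963, on chromosome 19 1.84 and 0.798, and on chromosome 22 2.11 and 0.228. On chromosome 8 they were 0.905 and 1.05. In the HOXD cluster the number of peaks was 0.714 and 1.67 times that of vehicle, and in the zinc finger clusters of 19q13 1.64 and 0.5 times. The H3K27me3 ratios of single chromosomes and intervals rest on few peaks, and their intervals overlapped between treatments.

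The relation of the H3K9me2 chromosome shift with gene density (rho = 0.47, bootstrap interval 0.30 to 0.59) was weighed against 3 technical explanations. The direction of the shift on autosomes also followed chromosome length, for which no correlation was computed, so length remains an alternative to gene density. The bootstrap intervals cover the sampling of peaks and not the spread between chromosomes. Peaks close to the caller's threshold did not carry the relation with gene density, since rho was 0.65 (0.40 to 0.73) among peaks with a −log10 q of 5 or more. A changed copy number in the A-366 culture would raise the reads per 10 kb around peaks, relative to the library, on the chromosomes whose share rose. The rank correlation of the 2 ratios was negative (rho = -0.46, interval -0.58 to 0.11), with an interval that reached positive values. Reads were taken at called peaks only, so additional weak peaks could lower the median on a chromosome that gained peaks. This comparison therefore cannot decide on copy number. A shift common to both antibodies would appear in the H3K27me3 libraries, where rho was -0.60 (-0.67 to 0.08) over 21 autosomes. Chromosome 21, without a vehicle peak, was left out. That rho rests on few peaks, with 12 in vehicle and 10 after A-366 on chromosome 16, 25 and 25 on chromosome 19, and 7 and 2 on chromosome 22. It therefore argues only weakly against a common shift. A changed copy number also stays open. So do a larger share of untargeted cutting in open chromatin in this one H3K9me2 library and an effect of A-366 on where H3K9me2 lies, because no control or second library was analysed here.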

How the results depend on the processing

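The results on gene density, gene cluster intervals and chromosome ends, with their alternatives, and the chance shifts of 50 to 500 kb were chosen after seeing the data. The H3K9me2 ratios of A-366 over vehicle depended on the threshold. The peak number ratio was 0.964 with a −log10 q of 3 or more, 0.784 with a fold of 5 or more, and reversed to 1.36 with a −log10 q of 5 or more. The covered length ratio, 0.995 with all peaks, reversed to 1.07 and 1.503 at these q limits and to 1.04 with peaks within 5 kb merged, and was 0.881 with a fold of 5 or more. For H3K27me3 the 2 ratios fell to 1.10 and 1.07 with a fold of 5 or more. The shares of shared peaks (vehicle, then A-366) were 17.7% and 19.7% for H3K9me2 with 50% reciprocal overlap, 27.04% and 30.4% within 1 kb, 25.8% and 25.7% with equal numbers of the strongest peaks, and 22.9% and 16.9% with a −log10 q of 5 or more in both lists. With a −log10 q of 3 or more the A-366 share was 25.5%. For H3K27me3 they were 45.4% and 36.2% with 50% reciprocal overlap, 64.1% and 51.1% within 1 kb, and 51.7% and 51.7% with equal numbers. The overlap of the marks over chance, 1.63 in vehicle and 0.515 after A-366, was 0.496 and 0.225 within 1 kb. Of these the A-366 count, 4 peaks, lay below each of the 100 shifts (9 to 27), and the vehicle count, 8, inside their range (6 to 28). With 50% reciprocal overlap both values were above 1, at 2.98 in vehicle and 1.60 after A-366. The rank correlation of the H3K9me2 chromosome shift with gene density rose to 0.647 with a −log10 q of 5 or more and was 0.325 without chromosomes 19 and 22. Of the alternatives of these results, named here or not, 33 stayed within the interval of the main value, 23 left it and 4 reversed. No reversal was called for the overlap of the marks, which rests on few peaks. Its values that crossed 1 are among the 23: 0.496 in vehicle within 1 kb and 1.60 after A-366 with 50% reciprocal overlap. The 33 include all contigs and the rows as deposited, and these counts leave out gene cluster intervals, chromosome ends and chance shares. For covered length the interval was given the relative width of that of the peak number. Of 32 alternatives of the ratios in the gene cluster intervals 30 stayed within the interval. The 2 that left it were the MHC class II region (0.222) and the zinc finger clusters of 19q13 (1 instead of 1.64), both with a fold of 5 or more. For chromosome ends the ratios within 10 Mb (1.41) and with a −log10 q of 5 or more (1.83) left it. Shifts of 50 to 500 kb raised the chance share of H3K27me3 peaks to 0.0679% and 0.0675%. They raised that of H3K9me2 peaks to 0.713% and 0.791%, so the observed overlap was 34.8 and 34.7 times this chance level. The cause of these changes was not tested. All contigs and the rows as deposited gave the main values, since the lists hold no other contigs and no overlapping rows. Promoter and gene list alternatives were not run, since no annotation of the build was used here. Depth limits single H3K9me2 peaks, with a median summit of 10 or 12 reads.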

Other observations

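The comparison of chromosome ends, its test and the test of extra copies of chromosome 8 were chosen after the values behind them had been seen.

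H3K9me2 peaks lay closer to chromosome ends after A-366. Of the A-366 peaks 9.74% (95% interval 9.31 to 10.2%) lay within 5 Mb of the start of a chromosome or of its last peak, and of the vehicle peaks 5.98% (5.66 to 6.31%), a ratio of 1.63. The ratio was 1.83 among peaks with a −log10 q of 5 or more and 1.41 within 10 Mb. The hypothesis that this only followed the shift of peaks between chromosomes was tested on the 10 chromosomes whose share of the peaks fell. There the ratio was 1.64 (7.93% against 4.84%), which argues against it for these chromosomes. The reverse, that peaks near ends raised the share of short chromosomes, was not examined. Untargeted cutting in open chromatin stays open here too, since no control was analysed. For H3K27me3 the shares within 5 Mb were 6.85% after A-366 and 8.33% in vehicle, with overlapping intervals.

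Chromosome 8 held the highest density of H3K9me2 peaks in both libraries, with 14.1 peaks per Mb in vehicle and 11.5 after A-366, against a median of 5.67 and 5.79 on the other autosomes. A few dense regions do not account for it, since the 10 richest bins held at most 18.3% of its peaks. Extra copies of chromosome 8 are a candidate explanation, since a caller without a control counts more reads on a gained chromosome, and the reads per 10 kb around its peaks were 1.40 and 1.43 times the median of the other autosomes. That ratio was also raised on chromosome 19, at 1.36 and 1.27, and was 0.675 and 0.643 on chromosome X. The peak density on chromosome 19 was 4.88 per Mb in vehicle and 8.07 after A-366. The copy number of chromosome 19 was not measured here, so its ratio does not argue against extra copies of chromosome 8. In the H3K27me3 libraries chromosome 8 had 1.36 and 1.45 times the median peak density, with read ratios of 0.769 (bootstrap interval 0.595 to 1.22) and 1.09 (0.866 to 1.63). On chromosome X, with 4 and 10 H3K27me3 peaks, the read ratios were 1.67 and 0.846, so they vary widely in these short lists. Extra copies and more H3K9me2 on chromosome 8 both stay open.

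The low overlap of H3K9me2 peaks between treatments may in part reflect weak peaks close to the threshold. The share of vehicle peaks with an overlap was 2.20 times higher in the highest quintile by −log10 q than in the lowest, and the highest reached 38.8% of vehicle and 48.9% of A-366 peaks (85.3% and 82.1% for H3K27me3). Removing peaks with a −log10 q under 5 from both lists did not raise the share, which was 22.9% of vehicle and 16.9% of A-366 peaks, but it also removed possible partners. Unequal list lengths could account for little of it, since the lists held 20384 and 18295 peaks. Equal numbers raised the vehicle share by only 0.929 percentage points and lowered the A-366 share from 27.5% to 25.7%. Trimming lists this close in length could not raise the vehicle share by much, so this comparison was not a real test. How much of the remainder comes from A-366 and how much from sampling stays open, because no second vehicle library was analysed here to give the overlap without treatment.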
